A study of Mus musculus with 70 samples.

How the data were processed

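Populations of 100 cells were sorted by flow cytometry from mouse bone marrow straight into lysis buffer in multiwell plates, per the labels' protocols. Libraries were made by CEL-seq, which amplifies polyadenylated RNA linearly and reads a tag near the 3′ end of each transcript. The labels' protocols record magnetic bead clean-ups in place of columns, a DNase step before fragmentation, Covaris fragmentation, and no phosphatase or polynucleotide kinase step. The deposited values are raw read counts per gene under Entrez identifiers, in 1 table per batch. Per the submitters' processing notes, base calling used CASAVA 1.8.2, the reads were placed on the mouse build mm10 and counted with featureCounts, and limma and edgeR (3.8.2 and 3.22.0) were used. The aligner is not given in the sources used here, and no molecular identifiers are stated, so intervals and bounds cover counting error only. Neither table names an ERCC spike-in among its 27179 genes. Symbols and coordinates came from the RefSeq annotation of GRCm38.p6, the same assembly, and 25275 identifiers (92.99%) matched. Unmatched genes were kept under their identifier. No value column was left without a sample (0).

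Samples were grouped by genotype and population from the labels. Of the 70 samples, 4 that the labels call technical repeats were added to their parent library. The 12 controls with spike-in RNA alone, the 6 libraries labelled Nfil, and 1 wild-type CILP library of batch 2 that the submitters call an outlier stayed out of the main model, which held 47 libraries. Nfil was compared in a model of its own (25 libraries of batch 2). Replicates were numbered in accession order, so numbers only name libraries.

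Comparisons used edgeR 4.0.16 in R 4.3.3: a filter by group (filterByExpr, at least 10 counts and 15 in total), TMM scaling, and a robust quasi-likelihood fit of a mean per group plus a batch term, with 35 residual degrees of freedom. A group with 1 or 2 libraries is assumed to vary like the others. The filter left 10972 genes (7238 for Nfil), and the biological coefficient of variation was 109.7%. Genes were called at a Benjamini-Hochberg adjusted p under 0.05, which is the adjusted p given throughout. CPM values use the TMM-scaled totals. Where a group had 0 counts, a fold was given as a bound against 3 counts over that group. Targeted genes were also compared by exact 2-sided permutation tests of log2(CPM + 1).

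The 24 gene lists came from general knowledge of the field and not from these samples. They covered ILC regulators, genes of ILC groups 1, 2 and 3, B lineage, recombination and lymphoid priming, stem and multipotent progenitors, T lineage, Notch targets, TCF-1 and LEF-1 targets, E protein targets, cytokine receptors and homing molecules, cell cycle, MHC and antigen presentation, interferon response, and immediate early and heat shock genes. Markers of other cells covered myeloid, erythroid and megakaryocyte, mast with basophil and eosinophil, dendritic, plasma and mature B, and mature T cells. The rest were mitochondrial and sex-linked genes. Lists were tested with camera at a preset correlation of 0.01, called at an adjusted p under 0.05 over the lists, with camera at an estimated correlation, and with fry (limma 3.58.1).

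The genes named in each comparison were the targeted gene, the 14 key regulators in brief, and 2 to 4 members of each list with the smallest adjusted p. Added to these were up to 8 called genes higher and 8 lower with the largest fitted fold change, a mean of at least 20 CPM in the higher group and the same sign in each batch that holds both groups. Unnamed gene models, ribosomal protein genes and mitochondrial genes were passed over. A comparison with fewer than 5 called genes names all of them. Some genes that this rule selects are not reported here, although they stayed in all tests, lists and counts of called genes. Groups, models, lists and this rule, with all alternatives except 3, were fixed before the data were examined. Alternatives were DESeq2 1.42.0, its size factors in edgeR (resting on 382 genes without a 0), limma-voom with quality weights, no filter, no batch term, each batch alone, only the compared groups, the outlier put back, libraries under 20% of their batch median left out, and each library left out in turn.

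The procedure was tested on simulated data with the real means and totals. For CILP against CLP it recovered 50 of 50 genes raised 64-fold, 39 of 50 lowered 64-fold, and 31 and 17 of 50 at 8-fold, and 15 of 156 calls were of unchanged genes (9690 genes tested). With 2 knockout libraries falls were hard to call: 6 of 50 genes lowered 64-fold were recovered for the Id2 knockout in CILP, against 46 raised ones.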

Results

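Transcript counts were available for sorted mouse bone marrow progenitors of innate lymphoid cells (ILC), the tissue-resident lymphocytes that lack rearranged antigen receptors. Each sample held 100 cells, and 5 populations were sorted. They were CLP (in this field, common lymphoid progenitors), CLP expressing the integrin α4β7, CILP (common innate lymphoid progenitors), a population labelled ILCP, and ILC2P (progenitors of group 2 innate lymphoid cells). The labels do not tie ILCP to a sort gate, and the design text lists Sca1+ CILP as its remaining population. Cells came from wild-type mice and from mice lacking Id2, which encodes an inhibitor of E proteins, or Tcf7, which encodes the transcription factor TCF-1.

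The 70 samples made 66 libraries after 4 technical repeats were added to their parents, and 47 libraries, 31 of them wild type, entered the comparisons. Wild-type groups held 8 CLP, 5 α4β7+ CLP, 7 CILP, 3 ILCP and 8 ILC2P libraries. Tcf7 knockout groups held 5 CLP, 4 CILP and 2 ILC2P libraries, and Id2 knockout groups held 2 CLP, 2 CILP and 1 ILCP library. The libraries were made in 2 batches, with 22 of those used in batch 1 and 25 in batch 2. Id2 knockout libraries were all in batch 1 and Tcf7 knockout ILC2P libraries were all in batch 2. Total gene counts ranged from 19322 to 624668 (median 134985), with medians of 126234.5 in batch 1 and 149467 in batch 2. Wild-type ILC2P held 19322 to 80873 (median 66812.5), and Tcf7 knockout CILP had the lowest median, 56609. In 12 spike-in control wells, 51 to 9439 counts fell on genes (median 349.5). Some wells held Igha (24 of 311) and myeloid markers (581 of 9439). No label says replicates came from separate animals, so p-values measure a spread that may be technical. Counts of separate libraries of 1 group differed by 5.06 to 38.1 times their sampling noise (109 pairs), and technical repeats by 10.9 to 15.3 times (4 pairs). Values are CPM, given as mean ± SD over the libraries of a group. For libraries in a model, counts were scaled by the library total times its TMM factor, so a CPM is not a share of the library's counts. List calls given without a p of their own also held with an estimated correlation between genes.

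**Figure D1:**
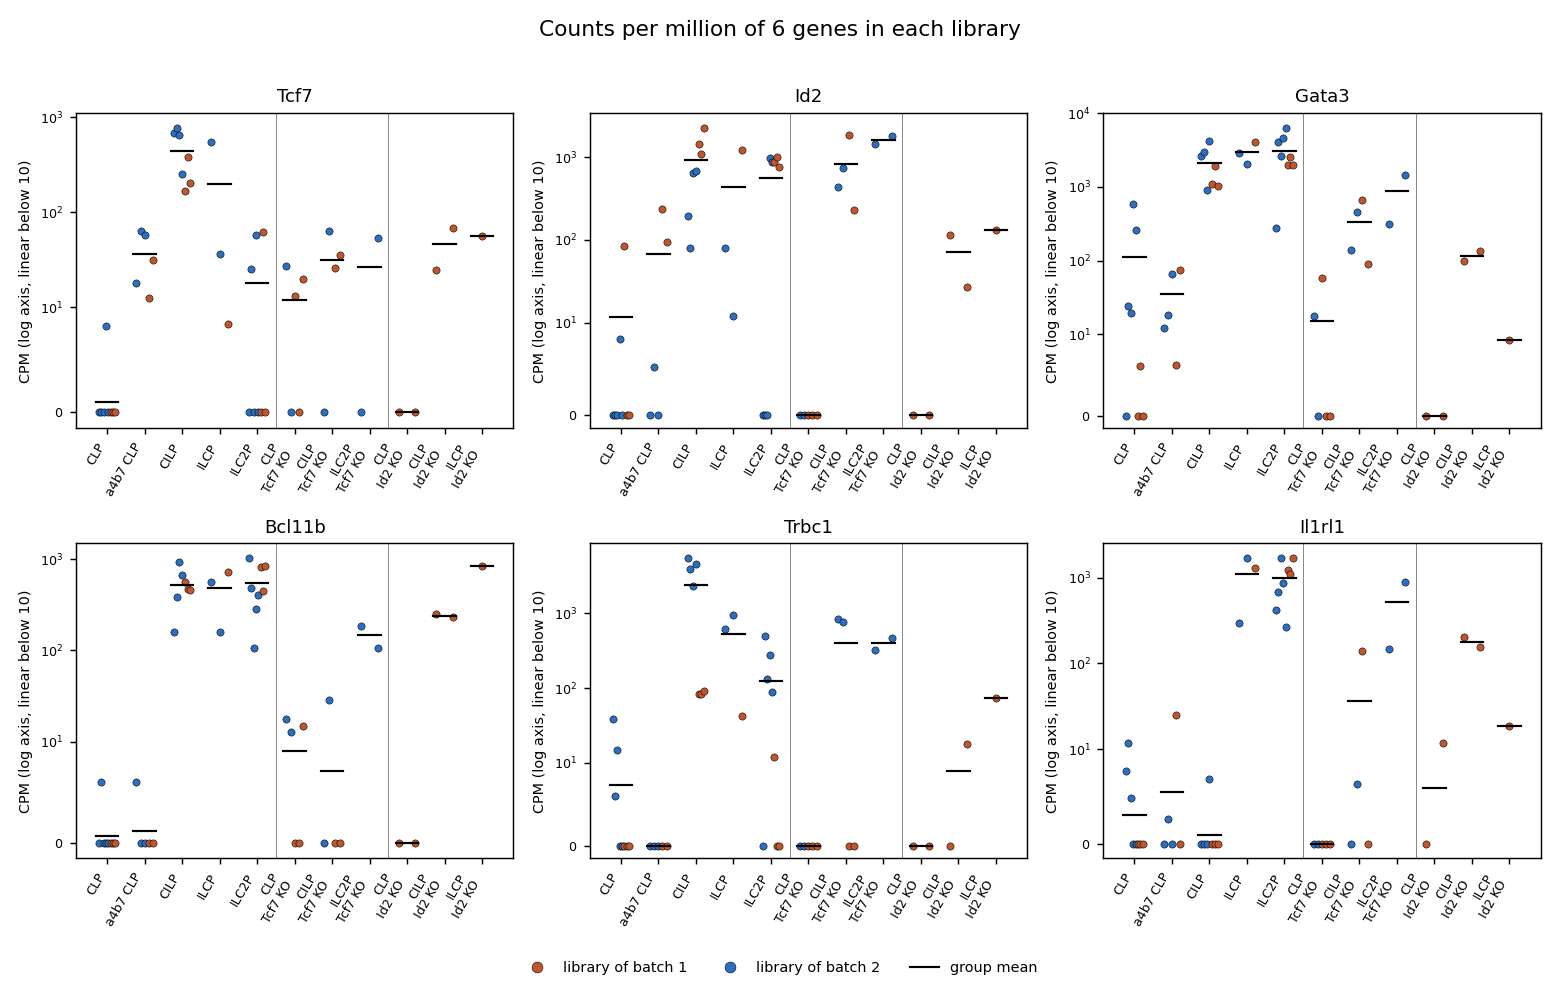
CPM of Tcf7, Id2, Gata3, Bcl11b, Trbc1 and Il1rl1 in each used library of the 11 groups, with batch 1 in red-brown, batch 2 in blue and the group mean as a line, on an axis that is linear below 10 and logarithmic above. Tcf7 and Bcl11b are near 0 in wild-type CLP (1.0 and 0.7 CPM) and high in wild-type CILP (445 and 517 CPM), and Il1rl1 is high in ILCP and ILC2P.

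The comparison of α4β7+ CLP (n = 5) with CLP (n = 8) asked which transcripts accompany the integrin within the CLP stage. Cpa3, which encodes the mast cell protease carboxypeptidase A3, was at 0 counts in all 8 CLP libraries and at 149 ± 168 CPM in α4β7+ CLP (at least 40.2-fold higher, adjusted p = 0.000293), with counts in 5 of 5 libraries. Ccr2, a chemokine receptor gene, rose from 4.8 ± 5.3 to 89.4 ± 137 CPM (adjusted p = 0.011) and Tpra1 from 5.5 ± 6.6 to 357 ± 699 CPM (adjusted p = 0.00963). Rag1, which encodes a subunit of the antigen receptor recombinase, fell from 500.4 ± 149.7 to 8.4 ± 11.7 CPM (adjusted p = 0.0138). The unnamed gene Entrez_100503944 also fell (log2 fold change −7.085, adjusted p = 0.0452). Tcf7 did not pass, at 36.3 ± 22.8 against 1 ± 2.9 CPM (adjusted p = 0.138). Id2 was at 66.8 ± 102 against 11.6 ± 29.7 CPM (adjusted p = 0.76) and Gata3 at 35.2 ± 32 against 112 ± 212 CPM (adjusted p = 0.917). The early B lineage factor Ebf1 was at 0 against 56.7 ± 76.4 CPM (adjusted p = 0.173), and Il7r, Flt3, Nfil3 and Ets1 did not pass either.

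Genes of the early B lineage were lower as a group (0 of 18 tested called, 2 lower adjusted over the list alone), as were genes activated by E proteins (1 of 14 tested lower, 3 adjusted over the list alone), the called member being Rag1. Other calls held with a preset correlation and were lost with an estimated one. Recombination genes (1 of 14 tested lower, 1 adjusted over the list alone, adjusted p = 0.133 with an estimated correlation) and Notch-responsive genes (0 of 6 tested called, 1 lower adjusted over the list alone, adjusted p = 0.133 with an estimated correlation) were lower. Mitochondrial transcripts (no member called, adjusted p = 0.38 with an estimated correlation) were lower too. Cell cycle genes (no member called, adjusted p = 0.27 with an estimated correlation) and myeloid markers (0 of 17 tested called, 6 higher adjusted over the list alone, adjusted p = 0.449 with an estimated correlation) were higher. Myeloid markers took 1.14% of the counts of α4β7+ CLP replicate 4 and at most 0.06% of the other 4 libraries.

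In edgeR, 3 genes rose and 2 fell among 10972 tested, and the median log2 fold change of all genes was 0.07. DESeq2 called 6 higher and 8 lower, a share of 42.9% higher against 60% in edgeR. Within batch 1 alone 2 genes passed, and within batch 2 alone 0 passed in edgeR (831 genes had an unadjusted p under 0.05 in both batches together, and limma-voom called 28). A fit of only the compared groups tested 3836 genes, 1 of the 5 among them, and called 3, all lower, including Rag1. The count was 3, 2 and 3 without α4β7+ CLP replicate 1, 3 or 5. Tpra1 was lost without replicate 3 (log2 2.74, adjusted p = 0.771), Ccr2 without replicate 4 (2.38, 0.283), and Rag1 without replicate 1, 3 or 5 (−5.46, up to 0.155). Cpa3 passed in each of those fits.

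The step from CLP (n = 8) to CILP (n = 7) asked which genes separate the innate lymphoid progenitor from its precursor stage. Transcription factor genes of the ILC and T lineages rose. Tcf7 went from 1 ± 2.9 to 445 ± 253 CPM (adjusted p = 9.85e-08) and Gata3 from 112 ± 212 to 2120.1 ± 1231 (adjusted p = 0.0032). Zbtb16, which encodes PLZF, rose from 1 ± 3 to 339 ± 111 (adjusted p = 2.04e-06), and Tox from 27.6 ± 33.4 to 590.2 ± 228 (adjusted p = 7.43e-05). Bcl11b, a zinc finger factor of T and group 2 ILC development, rose from 0.7 ± 2.1 to 517 ± 237 CPM (adjusted p = 6.54e-13). Id2 rose from 11.6 ± 29.7 to 916 ± 766 CPM (adjusted p = 0.000633) and Ets1 from 182 ± 65 to 986 ± 1032 (adjusted p = 0.000661). The nuclear receptor gene Rora was at 0 in CLP and rose at least 63.1-fold. The B lineage adaptor gene Blnk fell from 558 ± 245 CPM to 0 (at least 274-fold lower, adjusted p = 2.89e-10), and the cytokine receptor gene Flt3 fell from 401 ± 147 to 3.7 ± 9.8 CPM (adjusted p = 2.04e-07). Ebf1 fell from 56.7 ± 76.4 to 0.5 ± 1.4 CPM (adjusted p = 0.0152).

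Other genes with large fitted rises were Cela1 (at least 99.5-fold), Cpa3 (at least 92.1-fold), Nipal1 (at least 72.5-fold), Ikzf3, which encodes the Ikaros family factor Aiolos (at least 96.8-fold), and Pdcd1, which encodes the inhibitory receptor PD-1 (at least 89.3-fold), all at 0 in CLP. Trbc1, a T cell receptor β constant gene whose reads can be shared with Trbc2, rose from 7.4 ± 13.6 to 2358 ± 2325 CPM (adjusted p = 8.51e-15). Its level depended on the batch, with 83.1 to 91.5 CPM in the 3 CILP libraries of batch 1 and 2332 to 5495 CPM in the 4 of batch 2. Cox6a2 fell from 616 ± 224 to 2.7 ± 7 CPM, and Il12a, Myl4, Shisa8, Fads3, Drc7 and Hpse fell to 0 (by at least 37.4-fold to at least 74.3-fold). Il7r, Kit and Nfil3 did not pass (adjusted p = 0.264, 0.413 and 0.42).

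ILC regulators were higher in CILP (12 of 15 tested higher, 13 adjusted over the list alone). In the group 2 list (7 of 16 tested higher, 8 adjusted over the list alone) the costimulator gene Icos rose from 11.8 ± 19.6 to 487 ± 417 CPM and the arginase gene Arg1 rose at least 57.1-fold. In the list of group 1 ILC and natural killer cells (9 of 17 tested higher, 13 adjusted over the list alone) the chemokine gene Ccl5 rose from 15.2 ± 35.3 to 2675 ± 1169 CPM, and Eomes rose at least 31.1-fold. In the group 3 list (3 of 13 tested higher, 6 adjusted over the list alone) the lymphotoxin gene Ltb rose from 22.3 ± 36.5 to 225 ± 116 CPM. T lineage genes were higher (7 of 16 tested higher, 9 adjusted over the list alone), among them Thy1 (5.1 ± 9.8 to 327 ± 402 CPM). TCF-1 targets (8 of 16 tested higher, 9 adjusted over the list alone) and mature T cell markers (1 of 6 tested higher, 1 adjusted over the list alone, Trbc1) were higher too.

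Genes of the B lineage fell (1 higher and 9 lower of 18 tested, 1 higher and 14 lower adjusted over the list alone), including Ly6d, a marker of B-biased CLP, from 3364 ± 1472 to 60.6 ± 91.1 CPM, while the member that rose was Lef1. Recombination and lymphoid priming genes fell (1 higher and 8 lower of 14 tested, 1 higher and 9 lower adjusted over the list alone). Among them Dntt, which encodes terminal transferase, fell from 8383 ± 3986 to 400.1 ± 608 CPM (adjusted p = 0.00439) and Rag1 from 500.4 ± 149.7 to 28.5 ± 63.3 (adjusted p = 0.00193). E protein targets fell (1 higher and 8 lower of 14 tested, 4 higher and 9 lower adjusted over the list alone). Stem and multipotent progenitor genes fell (4 of 15 tested lower, 1 higher and 5 lower adjusted over the list alone), with the transcriptional cofactor gene Lmo2 going from 351 ± 190.0 to 4.2 ± 4.9 CPM. Cell cycle genes fell (6 of 28 tested lower, 14 adjusted over the list alone). Dendritic cell markers fell (1 higher and 7 lower of 12 tested, 1 higher and 7 lower adjusted over the list alone), while Xcr1 rose. The call of the interferon list, lower, was lost (1 higher and 3 lower of 19 tested, 2 higher and 4 lower adjusted over the list alone, adjusted p = 0.202 with an estimated correlation).

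In edgeR 257 genes rose and 216 fell, 54.3% higher, and DESeq2 called 180 higher and 242 lower, 42.7% higher. Within batch 1 the counts were 62 higher and 106 lower, and within batch 2 they were 76 and 29. They were 89 and 93 of 3088 tested with only the compared groups. Of 62 named genes that passed, 56 passed in each of 15 fits that left out 1 library. Myb, Cd34, Hey1, Cdk1, H2-DMa and Zbp1 did not.

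Set against α4β7+ CLP (n = 5), CILP (n = 7) again carried high T and ILC transcripts. Trbc1 was at 0 in α4β7+ CLP (at least 1240.0-fold higher in CILP, adjusted p = 3.43e-13), Bcl11b rose from 1.2 ± 2.7 to 517 ± 237 CPM (adjusted p = 2.59e-09) and Ccl5 from 3 ± 5.4 to 2675 ± 1169. Gata3 rose from 35.2 ± 32 to 2120.1 ± 1231 CPM (adjusted p = 0.00526), Zbtb16 from 2.6 ± 5.8 to 339 ± 111 (adjusted p = 0.000828) and Ets1 from 39.8 ± 22.7 to 986 ± 1032 (adjusted p = 3.57e-07). Rora, at 0 in α4β7+ CLP, rose at least 66.4-fold. Il2rg, which encodes the common γ chain of cytokine receptors, rose from 23.9 ± 22.3 to 395 ± 148 CPM (adjusted p = 0.000315). Blnk (at least 109-fold lower), Myzap (at least 88.3-fold), Fads3 (at least 83.8-fold), Il12a (at least 54-fold) and Ap4m1 (at least 30.6-fold) fell to 0, and Cox6a2 fell from 1013 ± 572 to 2.7 ± 7 CPM. Flt3 fell from 302 ± 134 to 3.7 ± 9.8 CPM (adjusted p = 2.51e-06). Tox, Il7r and Kit did not pass (adjusted p = 0.0522, 0.1 and 0.173).

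ILC regulators (10 of 15 tested higher, 12 adjusted over the list alone) and group 2 genes (6 of 16 tested higher, 7 adjusted over the list alone) were higher in CILP. Group 1 and natural killer genes (4 of 17 tested higher, 8 higher and 1 lower adjusted over the list alone) and group 3 genes (4 of 13 tested higher, 5 adjusted over the list alone) were higher. So were T lineage genes (5 of 16 tested higher, 9 adjusted over the list alone), TCF-1 targets (7 of 16 tested higher, 10 adjusted over the list alone) and mature T cell markers (1 of 6 tested higher, 1 adjusted over the list alone). Cell cycle genes fell (8 of 28 tested lower, 19 adjusted over the list alone), with the cyclin gene Ccna2 going from 308 ± 166 to 4 ± 7.8 CPM. Dendritic cell markers fell (1 higher and 7 lower of 12 tested, 1 higher and 8 lower adjusted over the list alone). Recombination genes fell (1 higher and 4 lower of 14 tested, 2 higher and 7 lower adjusted over the list alone). Calls of 3 lists were lost. These were B lineage genes (1 higher and 4 lower of 18 tested, 1 higher and 7 lower adjusted over the list alone, adjusted p = 0.0917 with an estimated correlation) and myeloid markers (no member called, adjusted p = 0.32 with an estimated correlation), both lower, and mitochondrial transcripts (no member called, adjusted p = 0.515 with an estimated correlation), higher.

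In edgeR 100 genes rose and 158 fell. The counts were 30 and 79 within batch 1 and 18 and 13 within batch 2. The total of 258 went to 169 without α4β7+ CLP replicate 1 and to 147 without replicate 2. Of 55 named genes, 42 passed in each of 12 fits that left out 1 library. Myzap was lost without α4β7+ CLP replicate 1 (log2 fold change −1.88, adjusted p = 0.604) and Ap4m1 without replicate 5 (−5.71, adjusted p = 0.0986). Tcf7 (from 36.3 ± 22.8 to 445 ± 253 CPM, adjusted p = 0.0308) was lost in 9 of them (adjusted p up to 0.092), and so was Id2 (from 66.8 ± 102 to 916 ± 766 CPM, adjusted p = 0.0433, up to 0.124).

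In the libraries labelled ILCP (n = 3), genes of group 2 ILC were higher than in CILP (n = 7). Il1rl1, which encodes the interleukin-33 receptor ST2, rose from 1 ± 2.6 to 1103 ± 727 CPM (adjusted p = 5.77e-12). Rnf128, an E3 ubiquitin ligase gene, rose from 1.1 ± 2.8 to 1187 ± 1135 (adjusted p = 2.32e-13). Il2ra, which encodes the interleukin-2 receptor α chain, rose from 1.1 ± 2.8 to 329 ± 129 (adjusted p = 1.1e-05) and the leukotriene receptor gene Cysltr1 from 0.8 ± 1.5 to 298 ± 77.6 (adjusted p = 0.00012). Ly6a, the gene of Sca-1, rose from 7.3 ± 9.5 to 629.5 ± 388 CPM (adjusted p = 1.39e-05). Igfbp4 fell from 1618 ± 728 to 38.9 ± 34.9 CPM (adjusted p = 1.39e-05) and Plac8 from 943 ± 477 to 89 ± 89.7 (adjusted p = 0.00268). The survival gene Bcl2 fell from 1952 ± 504 to 206 ± 119.6 CPM (adjusted p = 0.00976). None of 14 key regulators was called in edgeR. Tcf7 was at 198 ± 304 against 445 ± 253 CPM (adjusted p = 0.679) and Id2 at 439.8 ± 684 against 916 ± 766 (adjusted p = 0.672). Gata3 was at 2999.7 ± 1018 against 2120.1 ± 1231 (adjusted p = 0.912), with adjusted p = 1 for Bcl11b and 0.335 for Kit.

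The group 2 list was higher (3 of 16 tested higher, 6 adjusted over the list alone). Calls of 4 lists were lost. ILC regulators (0 of 15 tested called, 1 lower adjusted over the list alone, adjusted p = 0.274 with an estimated correlation), group 1 genes (no member called, adjusted p = 0.274 with an estimated correlation) and mitochondrial transcripts (no member called, adjusted p = 0.309 with an estimated correlation) were lower. Immediate early and heat shock genes (1 of 18 tested higher, 5 higher and 1 lower adjusted over the list alone, adjusted p = 0.327 with an estimated correlation) were higher. They took 1.97 ± 1.98% of the counts in ILCP and 0.489 ± 0.167% in CILP, and their called member Junb, an AP-1 subunit gene, was at 2189 ± 2374 against 193 ± 151 CPM. Erythroid and megakaryocyte markers took 2.201% of the counts in ILCP replicate 1 and at most 0.001% in the other 2. The haemoglobin gene Hba-a1, whose reads can be shared with its copy Hba-a2, had counts in that library alone (1980.0 ± 3429 CPM over the group), and so did Ccna2 (184 ± 319 CPM).

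In edgeR 34 genes rose and 7 fell, 82.9% higher, against 53 and 39, or 57.6%, in DESeq2. The median log2 fold change of all genes was −0.27. Within batch 1, with 1 ILCP library, 17 rose and 9 fell, and within batch 2 the counts were 6 and 2. The total of 41 went to 19 without ILCP replicate 2 and to 26 without CILP replicate 3. Il1rl1, Rnf128, Cysltr1, Il2ra, Ly6a, Igfbp4 and Plac8 passed in each of 10 fits that left out 1 library, and 12 other named genes did not. Without ILCP replicate 1 the log2 fold change of Hba-a1 was −0.46 and that of Ccna2 −2.65. Bcl2 was lost without ILCP replicate 2 or 3 (−2.79, adjusted p up to 0.122), and Junb without replicate 2 (2.05, 0.537).

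ILC2P (n = 8) compared with CILP (n = 7) showed the step to a later progenitor. Rnf128 rose from 1.1 ± 2.8 to 1821 ± 754 CPM (adjusted p = 2.77e-16) and Il1rl1 from 1 ± 2.6 to 991 ± 537 (adjusted p = 7.3e-13). Il2ra rose from 1.1 ± 2.8 to 407 ± 245 (adjusted p = 2.98e-07) and Ly6a from 7.3 ± 9.5 to 1033 ± 496 (adjusted p = 9.7e-08). The lectin-like receptor gene Klrg1 rose from 0.3 ± 0.7 to 413 ± 644 CPM, Cysltr1 from 0.8 ± 1.5 to 339 ± 245, and Pard3 from 0 (at least 240.0-fold). Transcripts of the earlier progenitor fell: Igfbp4 from 1618 ± 728 to 3.6 ± 10.2 CPM (adjusted p = 3.58e-17), Tcf7 from 445 ± 253 to 18.1 ± 27.1 (adjusted p = 0.00102) and Tox from 590.2 ± 228 to 33.7 ± 53.5 (adjusted p = 0.000381). Zbtb16, with 3 counts in ILC2P, was at 7.4 ± 12.3 against 339 ± 111 CPM (adjusted p = 0.000381). Rora fell to 6 ± 16.9 CPM, and the stem cell factor receptor gene Kit from 282 ± 147 to 40.1 ± 59.3 (adjusted p = 0.0286). Gata3 (3075 ± 1901 against 2120.1 ± 1231 CPM, adjusted p = 0.779), Bcl11b (551 ± 313 against 517 ± 237, adjusted p = 0.982) and Id2 (564 ± 472 against 916 ± 766, adjusted p = 0.951) did not pass. Id2 was at 0 counts in ILC2P replicates 1 to 3 and at 769 to 1002 CPM in the other 5.

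Several genes reached 0 in ILC2P: the cytotoxic granule gene Nkg7 (at least 51.9-fold lower, adjusted p = 1.32e-08), Pdcd1 (at least 34.2-fold), Tmsb15a (at least 74.1-fold) and Xkrx (at least 22.2-fold). Group 1 and natural killer genes fell as a list (8 of 17 tested lower, 1 higher and 12 lower adjusted over the list alone). ILC regulators (6 of 15 tested lower, 8 adjusted over the list alone) and T lineage genes (5 of 16 tested lower, 7 adjusted over the list alone) fell too. In the T lineage list Trbc1 fell from 2358 ± 2325 to 124 ± 175 CPM. The group 2 list was higher (4 higher and 2 lower of 16 tested, 5 higher and 3 lower adjusted over the list alone). Its members that fell were Rora and the interleukin-18 receptor gene Il18r1 (738 ± 239 to 15.6 ± 33.8 CPM).

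Calls of 4 lists, all higher, were lost. These were B lineage (1 higher and 2 lower of 18 tested, 2 higher and 3 lower adjusted over the list alone, adjusted p = 0.355 with an estimated correlation) and interferon-responsive genes (no member called, adjusted p = 0.219 with an estimated correlation). The others were immediate early and heat shock genes (2 of 18 tested higher, 6 higher and 1 lower adjusted over the list alone, adjusted p = 0.107 with an estimated correlation) and myeloid markers (no member called, adjusted p = 0.392 with an estimated correlation). The median of the myeloid list was −0.09 although its test was upward. Mitochondrial transcripts took 23.59% of the counts of ILC2P replicate 1 and 2.322 to 10.469% of the other 7.

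In edgeR 121 genes rose and 463 fell, 20.7% higher, with a median log2 fold change over all genes of −0.55. With DESeq2 size factors in edgeR the counts were 160 and 231 (40.9% higher, median −0.23), and with the DESeq2 test 187 and 280 (40% higher, median −0.05), so falls are relative to that shift. Within batch 1 the counts were 64 and 123, and within batch 2 they were 15 and 78. Without the shallow ILC2P replicates 1 and 3 the total went from 584 to 326. It was 90 of 1245 tested with only the compared groups, where 64 of 101 full-set genes still tested passed. Of 48 named genes, 41 passed in each of 15 fits that left out 1 library. Kit did not (adjusted p up to 0.0536).

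**Figure D2:**
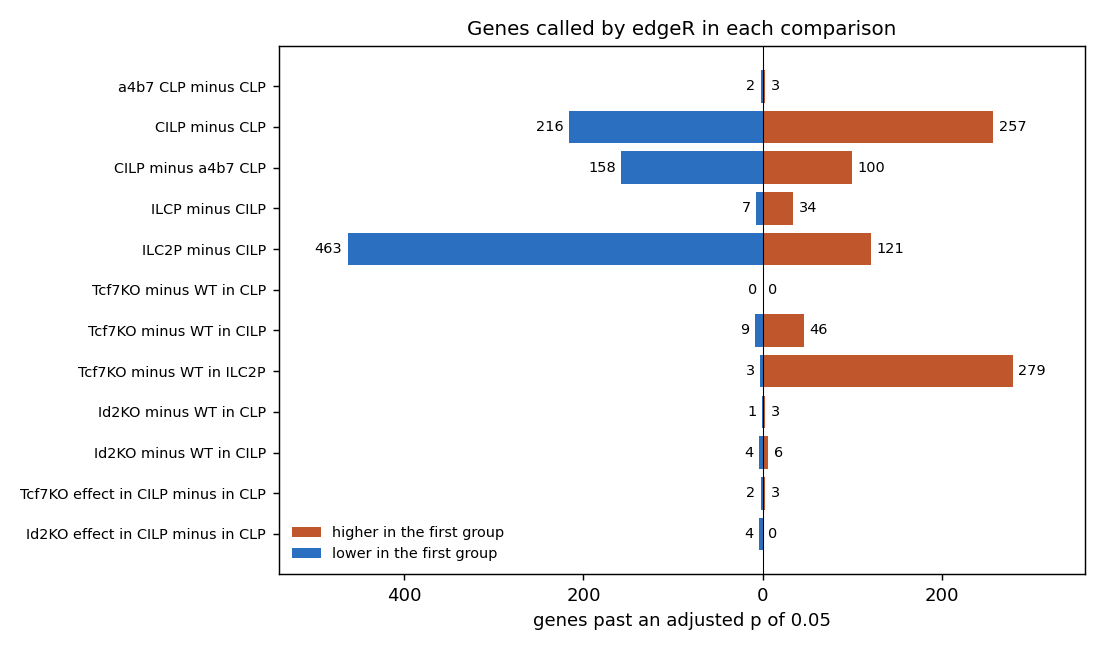
Number of genes called higher (bars to the right) and lower (bars to the left) at an adjusted p under 0.05 in edgeR, for 12 comparisons among the 47 libraries. ILC2P against CILP has 121 higher and 463 lower genes, and Tcf7 knockout against wild-type ILC2P has 279 higher and 3 lower.

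Tcf7 lies on chromosome 11 (mm10, 52246527 to 52283383, Entrez 21414). The labels do not give the deleted part, and a 3′ tag outside it would still be counted in a knockout, so remaining counts check the genotype only in part. In knockout CLP (n = 5) Tcf7 was at 26.8, 0, 13.1, 0 and 19.9 CPM in replicates 1 to 5, against 1 ± 2.9 CPM in wild-type CLP (n = 8, 1 count). The knockout level was the higher one (exact permutation test, 2-sided p = 0.035, the smallest possible being 0.000777, with an edgeR adjusted p of 0.565). In knockout CILP (n = 4) Tcf7 was at 0, 63.4, 25.5 and 35.6 CPM in replicates 1 to 4, and in wild-type CILP (n = 7) at 166.2 to 779.2 CPM (exact permutation test, 2-sided p = 0.00303, the smallest possible). In knockout ILC2P (n = 2) it was at 0 and 53.4 CPM, and in wild-type ILC2P (n = 8) at 18.1 ± 27.1 CPM (exact p = 0.867, the smallest possible being 0.0222).

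In Tcf7 knockout CLP edgeR called 0 of 10972 genes (713 had an unadjusted p under 0.05), DESeq2 called 1 and limma-voom 9. No list was called with the preset correlation, the smallest adjusted p being 0.0639 for interferon-responsive genes. Within batch 1 edgeR called 1 gene and within batch 2 it called 0. It called 1 gene when knockout replicate 2, 4 or 5 was left out.

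Among CILP, knockout of Tcf7 (n = 4) was accompanied by the loss of Bcl11b, which went from 517 ± 237 in wild type (n = 7) to 7.1 ± 14.3 CPM (adjusted p = 0.000446). Genes that CILP hardly expressed rose. Blk, a B cell kinase gene, went from 0 to 128 ± 37.6 CPM in 4 of 4 libraries (at least 48.1-fold, adjusted p = 0.00115) and Lmo2 from 4.2 ± 4.9 to 336 ± 361 CPM (adjusted p = 0.000446). Cybb, a phagocyte oxidase gene, had 1 count in wild type and 583 ± 714 CPM in the knockout (2 of 4 libraries, adjusted p = 5.76e-05). Igfbp4 fell from 1618 ± 728 to 165 ± 128 CPM (adjusted p = 0.00338). Arg1 (at least 28.2-fold), Xkrx (at least 28.6-fold) and Skap1 (at least 21.3-fold) fell to 0. Trbc1 was at 401 ± 464 against 2358 ± 2325 CPM (adjusted p = 0.0492). By batch it was at 0 in both knockout libraries of batch 1 and at 764 and 840 CPM in those of batch 2. Tcf7 itself had an edgeR adjusted p of 0.157. Gata3 (338 ± 272 against 2120.1 ± 1231 CPM, adjusted p = 0.411), Id2 (825 ± 733 against 916 ± 766, adjusted p = 1) and Zbtb16 (adjusted p = 0.62) did not pass.

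Further genes with large rises were Col5a1 (at least 41.2-fold) and Socs2 (212 ± 379.9 CPM, with 1 count in wild type). B lineage genes were higher as a list (5 of 18 tested higher, 11 adjusted over the list alone), among them the surrogate light chain gene Igll1 (at least 52.4-fold), Ebf1 (0.5 ± 1.4 to 187 ± 329.9 CPM) and Vpreb3 (3.2 ± 8.4 to 377 ± 504). E protein targets (3 of 14 tested higher, 4 adjusted over the list alone) and cell cycle genes (1 of 28 tested higher, 8 adjusted over the list alone) were higher too. So were group 3 genes (1 of 13 tested higher, 2 adjusted over the list alone), dendritic cell markers (1 of 12 tested higher, 2 adjusted over the list alone) and mast cell markers (0 of 9 tested called, 2 higher adjusted over the list alone). ILC regulators (1 of 15 tested lower, 2 adjusted over the list alone) and group 2 genes (1 higher and 2 lower of 16 tested, 1 higher and 3 lower adjusted over the list alone) were lower. T lineage genes (1 of 16 tested lower, 4 adjusted over the list alone), TCF-1 targets (1 of 16 tested lower, 2 adjusted over the list alone) and sex-linked genes (0 of 5 tested called, 1 lower adjusted over the list alone) were lower. The group 2 member that rose was Il1rl1 (36.7 ± 69.2 against 1 ± 2.6 CPM).

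Erythroid and megakaryocyte markers were higher (1 of 14 tested higher, 7 adjusted over the list alone). They took 2.112, 0.198, 0.03 and 10.202% of the counts in knockout replicates 1 to 4, and 0.104 ± 0.189% in wild-type CILP. Hba-a1, whose reads can be shared with Hba-a2, was at 578 ± 1082 against 0.5 ± 1.4 CPM, and Gata2, a factor of stem, mast and megakaryocyte cells, at 379 ± 433 against 16.1 ± 26.5 (adjusted p = 0.0321). Myeloid markers took 1.22, 0.105, 0 and 1.179% in the same replicates, and 0.038 ± 0.059% in wild type. The myeloid (0 of 17 tested called, 1 higher adjusted over the list alone, adjusted p = 0.0554 with an estimated correlation) and stem cell lists (2 of 15 tested higher, 3 adjusted over the list alone, adjusted p = 0.12 with an estimated correlation) lost their calls. So did the interferon (2 of 19 tested higher, 2 adjusted over the list alone, adjusted p = 0.12 with an estimated correlation) and plasma cell lists (0 of 11 tested called, 1 higher adjusted over the list alone, adjusted p = 0.0718 with an estimated correlation), all of them higher. Of lists that were lower, so did mature T cell markers (2 of 6 tested lower, 1 higher and 2 lower adjusted over the list alone, adjusted p = 0.0635 with an estimated correlation) and mitochondrial transcripts (0 of 14 tested called, 2 lower adjusted over the list alone, adjusted p = 0.434 with an estimated correlation).

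In edgeR 46 genes rose and 9 fell, and the median log2 fold change of all genes was −0.32. With DESeq2 size factors in edgeR 80 rose and 7 fell (median −0.06), and the DESeq2 test called 75 and 18 (median 0). Within batch 1 the counts were 45 and 20, with 12 genes shared with the full set, and within batch 2 edgeR called 0 genes (1215 genes had an unadjusted p under 0.05 with both batches). Without the doubted libraries (knockout CILP replicates 1 and 4, knockout ILC2P replicate 1 and wild-type ILC2P replicate 1) 2 genes were called. Blk passed (adjusted p = 0.0253), and Bcl11b (log2 fold change −4.73, adjusted p = 0.104) and Lmo2 (4.29, adjusted p = 0.151) did not. Cybb then had a log2 fold change of −0.86 and Blnk of −0.01. A fit of only the compared groups called 10 of 3695 genes, and 7 of 12 full-set genes still tested passed. The total of 55 went to 11, 7, 13, 13, 25, 8 and 16 without wild-type replicates 2 to 8 in turn, and to 9 and 31 without knockout replicates 1 and 4. Bcl11b, Blk, Lmo2 and Cybb passed in each of 11 fits that left out 1 library (adjusted p up to 0.0302), and the other 24 named genes did not. Igfbp4 was lost without knockout replicate 1 (log2 −2.96, adjusted p = 0.0518).

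Knockout ILC2P (n = 2) were compared with wild-type ILC2P (n = 8), which already had little Tcf7. Nkg7 was higher in the knockout, at 135 ± 8 CPM against 0 (at least 13.7-fold, adjusted p = 0.000391) and the interleukin-1 receptor gene Il1r1 at 373 ± 67.5 against 6.1 ± 12.5 (adjusted p = 0.00441). Il2rb, a receptor subunit gene for interleukins 2 and 15 with 2 counts in wild type, was at 268 ± 25.1 against 8.6 ± 24.4 CPM (adjusted p = 0.0124), and the antigen presentation gene Cd74 at 154 ± 1.1 against 5.1 ± 10.5. Hes1, a Notch-responsive gene, and Fmr1 fell to 0 (at least 20.8-fold and at least 15.7-fold, adjusted p = 0.0412 and 0.0438), and Ivns1abp fell from 1389.6 ± 914 to 256 ± 111 CPM. Bcl11b (146 ± 56.1 against 551 ± 313 CPM, adjusted p = 0.331), Gata3 (876 ± 793 against 3075 ± 1901, adjusted p = 0.534) and Id2 (1629.8 ± 234 against 564 ± 472, adjusted p = 0.308) did not pass.

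Among the large rises were immunoglobulin genes in replicate 1. Igha had 33107 counts in replicate 1, 267809 CPM, and 0 in replicate 2 (adjusted p = 7.32e-07 for the group). Iglc1 (at least 3450.0-fold), Iglv1 (at least 176-fold), Ighg2b (121298 ± 171541 CPM), Igkc (23434 ± 33107) and the antibody joining chain gene Jchain (43566 ± 61584) were high in the same library, and reads of immunoglobulin constant genes can be shared between copies. Slpi (at least 803-fold) and the clotting factor gene F13a1 (at least 13.4-fold) rose too, and lost their calls without that library (log2 fold change 0.82 and 2.86, adjusted p = 1 for both). Plasma cell markers took 20.065% of the counts of replicate 1, 0.023% of replicate 2 and at most 0.062% of any wild-type ILC2P library. In replicate 2, T lineage genes took 1.011% (0.069% in replicate 1, at most 0.206% in wild type) and mature T cell markers 0.71% (0.025% and 0.063%), with Trac at 3636 ± 5131 CPM over the group. Erythroid markers took 1.389% of replicate 1 and 0.013% of replicate 2, and myeloid markers 1.115% and 0.013%.

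With the preset correlation 11 lists were called, and each was lost with an estimated one. Plasma cell (7 of 11 tested higher, 8 adjusted over the list alone, adjusted p = 0.169 with an estimated correlation) and B lineage genes (5 of 18 tested higher, 14 adjusted over the list alone, adjusted p = 0.0813 with an estimated correlation) were higher. So were T lineage (3 of 16 tested higher, 5 adjusted over the list alone, adjusted p = 0.13 with an estimated correlation) and group 1 genes (3 of 17 tested higher, 9 adjusted over the list alone, adjusted p = 0.169 with an estimated correlation). Group 3 genes (5 of 13 tested higher, 8 adjusted over the list alone, adjusted p = 0.13 with an estimated correlation) and E protein targets (1 of 14 tested higher, 5 adjusted over the list alone, adjusted p = 0.13 with an estimated correlation) were higher. Cytokine receptors and homing molecules (4 of 22 tested higher, 6 adjusted over the list alone, adjusted p = 0.184 with an estimated correlation) and interferon-responsive genes (1 of 19 tested higher, 1 adjusted over the list alone, adjusted p = 0.169 with an estimated correlation) were also higher. Group 2 genes (1 higher and 1 lower of 16 tested, 1 higher and 1 lower adjusted over the list alone, adjusted p = 0.138 with an estimated correlation), immediate early and heat shock genes (no member called, adjusted p = 0.169 with an estimated correlation) and mitochondrial transcripts (no member called, adjusted p = 0.34 with an estimated correlation) were lower.

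In edgeR 279 genes rose and 3 fell, 98.9% higher, against 115 and 41, or 73.7%, in DESeq2. The median log2 fold change of all genes was 0.19, and −0.08 with DESeq2 size factors in edgeR. All knockout libraries were in batch 2, where edgeR called 52 genes, all higher. Many calls were lost without either library, which leaves 1. Without the doubted libraries 83 were called. With only the compared groups 2 genes were, out of 67 full-set genes still tested, and Il1r1 was lost (adjusted p = 0.319). Without replicate 1 the log2 fold changes of Igha, Ighg2b, Iglc1, Hbb-bs and Hba-a1 were −4.85, −4.95, −1.025, −0.97 and −0.06. Nkg7 and Il1r1 passed in each of 10 fits that left out 1 library (adjusted p up to 0.0462). Calls were lost with folds still large for Il2rb without either knockout library and Cd74 without replicate 1 (log2 5.76 and 5.67, adjusted p up to 0.0681 and 0.0612). They were lost for Hes1, Fmr1 and Ivns1abp without either or 1 of several wild-type libraries (log2 −7.13, −7.05 and −2.135, adjusted p up to 0.328, 0.333 and 0.507).

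**Figure D3:**
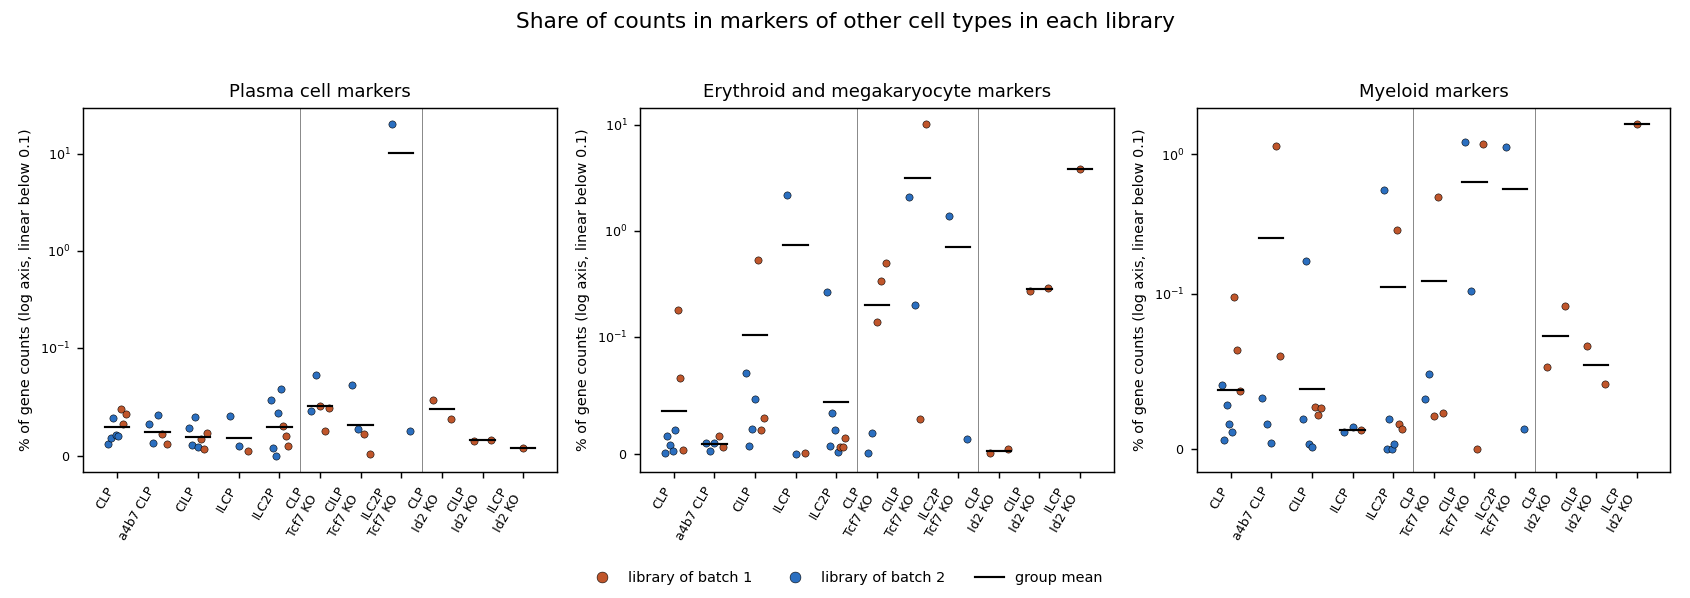
Share of the gene counts of each library, in percent, that falls on markers of plasma cells, of erythroid cells and megakaryocytes, and of myeloid cells, with the group mean as a line, on an axis that is linear below 0.1 and logarithmic above. Tcf7 knockout ILC2P replicate 1 stands at 20.065% for plasma cell markers, and Tcf7 knockout CILP replicate 4 at 10.202% for erythroid and megakaryocyte markers.

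The effects of the Tcf7 knockout in CILP and in CLP were compared by an interaction term. The effects differed for Bcl11b (log2 difference -7.79, adjusted p = 0.00314), Blk (8.19, adjusted p = 0.0255), Cybb (7.81, adjusted p = 0.0261), Lmo2 (6.27, adjusted p = 0.038) and Lmo4, a transcriptional cofactor gene (-3.07, adjusted p = 0.038). In CLP, Blk was at 42.2 ± 22.1 CPM in the knockout and 84.2 ± 83.1 in wild type, Lmo2 at 257 ± 392 and 351 ± 190, and Lmo4 at 165 ± 101 and 107 ± 45.5. In CILP, Lmo4 fell from 2547 ± 602 to 456 ± 368 CPM (adjusted p = 0.0144). For Tcf7 itself the difference was -6.75 (adjusted p = 0.0834). The fitted value of Blk rests on a group at 0 and is no bound. The B lineage list (1 of 18 tested higher, 8 adjusted over the list alone) and the sex-linked list (0 of 5 tested called, 2 lower adjusted over the list alone) differed between the stages. ILC regulators, TCF-1 targets, cell cycle genes, erythroid markers and dendritic cell markers lost their calls with an estimated correlation (adjusted p = 0.254, 0.254, 0.254, 0.312 and 0.263).

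Of the 5 genes called in edgeR, 3 had a positive difference, 60%, against 16 of 21, or 76.2%, in DESeq2, and the median difference of all genes went from −0.20 to 0.13. Within batch 1 edgeR called 20 genes and within batch 2 it called 0 (996 genes had an unadjusted p under 0.05 in the full fit, and limma-voom called 39). It called 14 with only the compared groups, the 5 included. The count went to 0 without knockout CLP replicate 5 and without the doubted libraries, where the difference of Cybb was −1.76. It was 1, 1, 1, 3 and 2 without wild-type CILP replicates 2, 3, 5, 6 and 7, and 3 without wild-type CLP replicate 4 or 8. It was 2, 8 and 1 without knockout CILP replicates 1, 2 and 4, and 1 and 2 without knockout CLP replicates 2 and 3. Bcl11b was lost only without knockout CLP replicate 5 (adjusted p = 0.0515 in 1 of 24 fits), Blk in 7 fits, Cybb in 10, Lmo2 in 13 and Lmo4 in 15.

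Id2 lies on chromosome 12 (mm10, 25093799 to 25096092, Entrez 15902), and the labels do not say which part was deleted. In knockout CLP (n = 2) it had 0 counts in both libraries, and in wild-type CLP (n = 8) it was at 11.6 ± 29.7 CPM (exact permutation test, 2-sided p = 0.822, the smallest possible being 0.0222). In knockout CILP (n = 2) it was at 116.4 and 27.1 CPM, and in wild-type CILP (n = 7) at 916 ± 766 CPM (exact p = 0.0556, the smallest possible being 0.0278). In batch 1 alone, which holds the knockout, wild-type CILP (n = 3) were at 1602 ± 618 CPM (exact p = 0.1, the smallest possible).

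In CLP, 3 genes rose and 1 fell in the knockout. Xist, the non-coding RNA of the inactive X chromosome, rose from 0.8 ± 2.2 to 1278 ± 142 CPM (adjusted p = 0.039), and the Y-linked gene Ddx3y fell from 301 ± 222 CPM to 0 (at least 37.8-fold, adjusted p = 0.039). The 4 knockout CLP and CILP libraries had 91 to 347 Xist counts and 0 Y-linked counts, while each of the 42 libraries of other genotypes had Y-linked counts and at most 4 Xist counts. Ccr2 rose from 4.8 ± 5.3 to 109 ± 115 CPM (adjusted p = 0.0455). The MHC class II gene H2-Eb1, with 3 counts in wild type, was at 317 ± 322 against 3.2 ± 6.3 CPM (adjusted p = 0.0455). The sex-linked list moved (1 higher and 1 lower of 5 tested, 1 higher and 3 lower adjusted over the list alone). The MHC (1 of 14 tested higher, 2 adjusted over the list alone, adjusted p = 0.198 with an estimated correlation) and dendritic cell lists (no member called, adjusted p = 0.0632 with an estimated correlation), both higher, lost their calls. So did immediate early and heat shock genes (no member called, adjusted p = 0.0656 with an estimated correlation) and mitochondrial transcripts (no member called, adjusted p = 0.299 with an estimated correlation), both lower.

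DESeq2 called 0 genes higher and 2 lower in this comparison, where 348 genes had an unadjusted p under 0.05 in edgeR, and edgeR with DESeq2 size factors called 1 higher and 1 lower (50% against 75%). Within batch 1 edgeR called 9 genes, and with only the compared groups 1, Xist. The count of 4 went to 2, 0, 2, 0 and 1 without wild-type replicates 1, 4, 6, 7 and 8, and to 2 and 0 without knockout replicates 1 and 2. No gene passed in each of 10 fits that left out 1 library, the highest adjusted p being 0.365 for Xist, 0.888 for Ddx3y, and 1 for Ccr2 and H2-Eb1, all without knockout replicate 2.

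In CILP, the Id2 knockout (n = 2) had 0 counts of Ccr2, against 748 ± 346 CPM in wild type (n = 7, at least 93.4-fold lower, adjusted p = 0.000516). Il18r1, with 3 counts in the knockout, was at 7.6 ± 2.1 against 738 ± 239 CPM (adjusted p = 0.0253), and Lmo4 fell from 2547 ± 602 to 252 ± 123 (adjusted p = 0.0367). Il1rl1 rose from 1 ± 2.6 to 178 ± 34.3 CPM (adjusted p = 0.000846) and Lmo2 from 4.2 ± 4.9 to 234 ± 50 (adjusted p = 0.00804). Ska1, a kinetochore gene, rose at least 65.9-fold and Col5a1 at least 10.5-fold, both from 0. Xist rose from 0 (at least 485-fold, adjusted p = 0.0147) and Ddx3y fell to 0 (at least 34.6-fold, adjusted p = 0.0147). Several key regulators did not pass. Gata3 was at 117 ± 26.6 against 2120.1 ± 1231 CPM (adjusted p = 0.713). Tcf7 was at 46.2 ± 30.6 against 445 ± 253 (adjusted p = 0.814) and Il7r at 129.6 ± 68.1 against 1449 ± 764 (adjusted p = 0.0805). Tox was at 47.9 ± 10.2 against 590.2 ± 228 (adjusted p = 0.404) and Id2 itself had an edgeR adjusted p of 0.595.

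ILC regulators were lower as a group (0 of 15 tested called, 6 lower adjusted over the list alone), and so were group 2 (1 higher and 1 lower of 16 tested, 1 higher and 5 lower adjusted over the list alone) and group 3 genes (0 of 13 tested called, 0 adjusted over the list alone). In the group 2 list Il1rl1 rose and Il18r1 fell. Stem and multipotent progenitor genes (1 of 15 tested higher, 4 adjusted over the list alone, Lmo2) and cell cycle genes (0 of 28 tested called, 9 higher adjusted over the list alone) were higher. Cell cycle genes took 0.637 ± 0.207% of the counts against 0.195 ± 0.087% in wild-type CILP. Mitochondrial transcripts were lower (0 of 14 tested called, 8 lower adjusted over the list alone), at 0.657 ± 0.384% against 5.076 ± 1.956%. The sex-linked list moved (1 higher and 1 lower of 5 tested, 1 higher and 4 lower adjusted over the list alone). Group 1 genes (no member called, adjusted p = 0.153 with an estimated correlation) and TCF-1 targets (0 of 16 tested called, 1 higher and 3 lower adjusted over the list alone, adjusted p = 0.126 with an estimated correlation), both lower, lost their calls. So did MHC genes (0 of 14 tested called, 2 lower adjusted over the list alone, adjusted p = 0.17 with an estimated correlation) and immediate early and heat shock genes (no member called, adjusted p = 0.309 with an estimated correlation), both lower. The higher lists that lost theirs were erythroid (no member called, adjusted p = 0.176 with an estimated correlation) and mast cell markers (0 of 9 tested called, 1 higher adjusted over the list alone, adjusted p = 0.0827 with an estimated correlation).

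In edgeR 6 genes rose and 4 fell, 60% higher, and DESeq2 called 11 and 33, 25% higher. Within batch 1, which holds both knockout libraries, 48 rose and 42 fell, with 7 genes shared with the full set. With only the compared groups 13 rose and 34 fell, and Il1rl1 was lost (adjusted p = 0.155). The total of 10 went to 6 without wild-type replicate 3 or 7, and to 1 and 4 without knockout replicates 1 and 2. Il1rl1 passed in each of 9 fits that left out 1 library (adjusted p up to 0.0452). The call of Ccr2 was lost without either knockout library (log2 −9.95, adjusted p up to 0.126), Lmo2 without replicate 1 (5.705, 0.126), and Il18r1 without either or wild-type replicate 3 (−6.65, up to 0.539), their folds being nearly as large as in the full fit.

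The effect of the Id2 knockout differed between CILP and CLP for 4 genes. Ccr2 (log2 difference -13.99, adjusted p = 9.22e-07) passed in both stages, lower in CILP and higher in CLP. H2-Eb1 (-14.21, adjusted p = 0.0134) passed in CLP but not in CILP (0 against 158 ± 131 CPM, adjusted p = 0.178). Lmo4 differed (-4.52, adjusted p = 0.0134), at 247 ± 27.4 against 107 ± 45.5 CPM in CLP. The gene model 1700113H08Rik (-13.95, adjusted p = 0.0134) was at 0 against 188 ± 68.8 CPM in CILP and at 58.6 ± 82.8 against 0 in CLP, and passed in neither (adjusted p = 0.247 and 0.104). Fitted differences against groups at 0 are no bounds. Stem cell, cell cycle, MHC, erythroid and mitochondrial lists lost their calls with an estimated correlation (adjusted p = 0.206, 0.206, 0.206, 0.415 and 0.415).

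EdgeR called 0 positive and 4 negative differences (528 genes had an unadjusted p under 0.05, and limma-voom called 201), and DESeq2 called 4 and 11, 26.7% positive. Within batch 1 edgeR called 35 genes, and with only the compared groups 12, the 4 included. Ccr2 passed in each of 19 fits that left out 1 library (adjusted p up to 0.0106). The count went to 1 without knockout CILP replicate 1 or 2 and to 2 without knockout CLP replicate 2, with H2-Eb1, Lmo4 and the gene model lost (adjusted p up to 1).

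The single Id2 knockout ILCP library (111413 counts, so that 3 counts make 26.9 CPM) has no replicate and was not tested against wild-type ILCP (n = 3). Id2 had 14 counts, 130.6 CPM, within the wild-type range of 12.1 to 1228.3. Gata3 had 1 count, 9.3 CPM, against 2999.7 ± 1017.6, Il1rl1 2 counts, 18.7 CPM, against 1103 ± 727, and Il2ra 0 counts against 329 ± 129. Erythroid markers took 3.874% of the counts and myeloid markers 1.646%, and the library had 28 Xist and 15 Y-linked counts.

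Genes gained at the CILP stage were followed in the knockouts with libraries that share no sample. The Id2 knockout libraries also differ from their controls in sex and in mitochondrial share (0.385 and 0.928% against 2.833 to 4.273%). A list of 76 genes higher in CILP than in CLP was taken from a fit of the wild-type libraries of batch 2 alone, and its 68 tested members were followed in CILP of batch 1. In the Id2 knockout (n = 2 against 3) their median log2 fold change was −2.44 (−2.40 with members at 0 set to their bound), while that of all genes was 0.12. Of the 68, 58 were negative and 12 fell, among them Icos, Bcl2, Tox and Ccr2 (23 adjusted over the list alone, fry p = 2.57e-05, camera p = 9.13e-05 with an estimated correlation). The fry p stayed between 2.94e-05 and 0.00107 when each library was left out. In the Tcf7 knockout (n = 2 against 3) the median was −0.83 (−0.63 at the bound) against −0.25 for all genes. There 47 members were negative and 3 fell, Icos, Bcl11b and Lmo4, with 2 higher and 6 lower adjusted over the list alone (fry p = 0.0138, camera p = 0.0848 with an estimated correlation). This fry p was 0.336 without knockout replicate 4 (median −0.47), the library with 10.202% erythroid markers, and 0.0547 without wild-type replicate 7, and the median was −2.81 without knockout replicate 3. The opposite list from that fit, 35 genes lower in CILP with 34 tested, had medians of 0.12 in the Tcf7 and 0.01 in the Id2 knockout (0.90 and 0.08 at the bound), tested upward (fry p = 0.0126 and 0.00966, camera p = 0.0287 and 0.254 with an estimated correlation). In the Tcf7 knockout these p were 0.187 and 0.224 without knockout replicate 4, 0.019 and 0.0677 without wild-type replicate 7, and 0.0528 and 0.0551 without replicate 8. In the Id2 knockout the fry p was 0.0523 without replicate 8. The medians ran from 0 to 0.556 and from 0 to 0.895, the highest without wild-type replicate 7.

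The libraries labelled Nfil, which the labels do not expand, come from a knockout that the submitters call unsuccessful. Nfil3 (chromosome 13, mm10, 52967209 to 52982878, Entrez 18030), the gene whose symbol begins so, had 0 counts in all 6. There 3 counts make 16 to 10135.1 CPM, so 0 does not show absence. In wild type of the same batch Nfil3 was at 20.6 ± 30.8 CPM in CLP (n = 5), 38.1 ± 32.1 in CILP (n = 4) and 2.5 ± 5.6 in ILC2P (n = 5). Against 2 libraries each, the exact permutation tests did not pass (2-sided p = 0.286, 0.0667 and 1, the smallest possible being 0.0476, 0.0667 and 0.0476). In Nfil CLP 1 gene was called, higher. In Nfil CILP 13 genes rose and 33 fell, but replicate 2 held 296 counts in all and the median of all genes was −3.98. Emilin3 (at least 691-fold) and Pou3f1 (2187 ± 3093 against 0.5 ± 1.1 CPM, 1 count in wild type) rose, each with counts in 1 of 2 Nfil libraries. Trbc1 fell from 4731 ± 1532 to 18.9 ± 26.7 CPM and Il7r from 1967 ± 1109.9 to 75.4 ± 107. In Nfil ILC2P 4 genes rose: Tmem189, Stat5a, Eri1 and Rrm1 (adjusted p = 0.000175, 0.0422, 0.021 and 0.0442).

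EdgeR tested 7238 genes in these comparisons. With only the compared groups it called 1 gene in CILP, and 0 in CLP and ILC2P, where 376 and 930 genes had an unadjusted p under 0.05 in the full fit. DESeq2 called 1 gene in CLP, 17 higher and 468 lower in CILP (3.5% higher against 28.3%, median −1.94) and 25 and 27 in ILC2P (48.1% higher against 100%, median −0.73 against −1.05). The CILP count was 157 without Nfil replicate 2 and 23, 25, 25 and 22 without wild-type replicates 2 to 5. The CLP count was 4 without Nfil replicate 1 and 2 without wild-type replicate 5, and the ILC2P count was 9 and 11 without Nfil replicates 1 and 2 and 1 without wild-type replicate 1, 3, 4 or 5. Tmem189 and Rrm1 had log2 fold changes of −3.96 and −4.41 without Nfil ILC2P replicate 1, and Ptpn13 and Zfp953 of −2.59 and −1.07 without Nfil CILP replicate 1. No list was called in CLP or ILC2P, and those called in CILP, such as ILC regulators and T lineage genes, both lower, were lost with an estimated correlation (adjusted p = 0.307 and 0.107).

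Over all comparisons 357 list tests were made. Of these, 116 were called with the preset correlation, 52 with an estimated one and 87 by fry, and none of the 116 changed direction with DESeq2 size factors. In Nfil CILP the B lineage, E protein, cell cycle and dendritic cell lists had medians and means opposite in sign to their test.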

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

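All tests of explanations in this part, the splits of the libraries included, were chosen after the results were seen.

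Knockout of Tcf7 in ILC2P gave 279 higher and 3 lower genes, in a comparison where falls were hard to call. Plasma cell RNA may account for the immunoglobulin part, as 8 of 12 plasma cell markers stood over 100 CPM in replicate 1 and above each wild-type ILC2P library (Igha 267809 CPM), while 2 of them average 20 CPM or more in wild-type ILC2P and 0 belong to another list. As a cause of all other calls, plasma cell RNA is argued against by 83 genes still called without replicate 1, and T cell RNA in replicate 2 by 179 still called without that library. Those fits share the spread of all groups, and with only the compared groups 2 genes passed. RNA of other cells in both libraries and an effect of the knockout cannot be told apart, because both would put B lineage markers above each wild-type library, which 18 of 20 did in replicate 1 and 6 in replicate 2.

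Id2 was at 0 counts in wild-type ILC2P replicates 1 to 3, and in wild-type CILP it was lower in replicates 2 and 3 (197 and 79.6 CPM) than in the other 5 (650.5 to 2286.3), with 84.9 CPM (4 counts) in the left-out replicate 1. Low depth is argued against, since 112.5 counts would have fallen on Id2 in the 3 ILC2P libraries at the lowest level of the other 5. A batch difference stays open: wild-type ILC2P of batch 2 reached 978.3 CPM, but ILCP 79 (1228.3 in batch 1). Mislabelled Id2 knockout libraries among the CILP are argued against by Il18r1, which was at 702.7 CPM or more in both and at 7.6 ± 2.1 CPM in the knockout. A difference in mice, plates or handling could remain, and no biological explanation was tested.

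Among the calls of the Id2 knockout, those of Xist and Ddx3y may come from female knockout mice, since the lowest Xist count among the 4 CLP and CILP libraries was 91, with no Y-linked count. For Ccr2, lower in knockout CILP and higher in knockout CLP, the interaction passed (adjusted p = 9.22e-07). A sex or strain effect and loss of Id2 cannot be told apart for it, because wild-type CLP held 6 Ccr2 counts and the CLP rise lost its call in 6 of 10 fits without 1 library (adjusted p up to 1). Nor can they for the other autosomal genes, because 0 of 42 libraries of the other genotypes had over 10 Xist counts. An effect of the lost Id2 stays open for these genes.

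A sample of splits of the same libraries into same-sized groups was fitted with the compared groups only. Chance is less likely where only the real split gave as many calls. That held for α4β7+ CLP against CLP (3 called, highest other split 1, of 100), CILP against CLP (182 and 1, of 100), CILP against α4β7+ CLP (207 and 3, of 99), ILCP against CILP (34 and 7, of 100), ILC2P against CILP (90 and 3, of 100) and Tcf7 knockout CILP (10 and 3, of 100). This concerns the counts, and of the 5 genes named for α4β7+ CLP 1 was tested in that fit. For Tcf7 knockout CLP, with a real count of 0, all 100 splits must give as many (highest other split 2), which says nothing about chance.

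The effects of a knockout differed between CILP and CLP by an interaction test for 9 genes, as log2 differences. They were −7.79 for Bcl11b, 8.19 for Blk, 7.81 for Cybb, 6.27 for Lmo2 and −3.07 for Lmo4 with Tcf7, and −13.99 for Ccr2, −13.95 for 1700113H08Rik, −14.21 for H2-Eb1 and −4.52 for Lmo4 with Id2.

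Of 64 tests for a single library far from the rest of its group, 11 singled one out, where chance does so in about 5%. Tcf7 knockout CILP replicate 2 had 432561 counts (the others 44089 to 63853). Mitochondrial transcripts took 23.59% of wild-type ILC2P replicate 1 (2.322 to 10.469% elsewhere), and the 10 largest genes 24.604% of α4β7+ CLP replicate 2 (6.846 to 10.039%). Myeloid markers took 0.492% of Tcf7 knockout CLP replicate 4 (0.021 to 0.048%), 1.14% of α4β7+ CLP replicate 4 (0.004 to 0.06%) and 0.171% of wild-type CILP replicate 3 (0.001 to 0.027%). Erythroid markers took 0.53% of wild-type CILP replicate 6 (0.007 to 0.069%), 0.179% of wild-type CLP replicate 6 (0.001 to 0.065%) and 0.264% of wild-type ILC2P replicate 1 (0.002 to 0.035%). Mast cell markers took 0.507% of wild-type CILP replicate 6 (0.005 to 0.056%) and 0.037% of wild-type ILC2P replicate 6 (0 to 0.014%).

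The wild-type CILP library that the submitters left out held 47089 gene counts, above the 51 to 9439 of the control wells.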

How the results depend on the processing

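The fits without robust estimation, without the doubted libraries (Tcf7 knockout CILP replicates 1 and 4, Tcf7 knockout ILC2P replicate 1, wild-type ILC2P replicate 1) and with 1 library left out of groups of 7 or 8 were chosen after the data were seen. Counts of called genes that moved by over 1.5 times, or a named gene that reversed, are given by setting. For each, the cause was not tested, except that fits of 1 batch or without libraries hold fewer samples and fits of the compared groups alone test fewer genes. Comparisons run in the order α4β7+ CLP against CLP (5 called), CILP against CLP (473), CILP against α4β7+ CLP (258), ILCP against CILP (41), ILC2P against CILP (584), Tcf7 knockout CLP (0), CILP (55) and ILC2P (282), Id2 knockout CLP (4) and CILP (10), the Tcf7 (5) and Id2 (4) interactions, and Nfil CLP (1), CILP (46) and ILC2P (4).

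DESeq2 called 14 for α4β7+ CLP against CLP and 92 for ILCP against CILP. It called 1, 93 and 156 for Tcf7 knockout CLP, CILP and ILC2P, 2 and 44 for Id2 knockout CLP and CILP, 21 and 15 for the Tcf7 and Id2 interactions, and 485 and 52 for Nfil CILP and ILC2P. Its size factors in edgeR gave 1 and 87 for Tcf7 knockout CLP and CILP, 2 for Id2 knockout CLP, 10 for the Tcf7 interaction and 9 for Nfil ILC2P. Limma-voom called 28, 729, 830 and 172 for the first 4 comparisons. It called 9 and 90 for Tcf7 knockout CLP and CILP, 24 and 527 for Id2 knockout CLP and CILP, and 39 and 201 for the interactions. For Nfil CLP, CILP and ILC2P it called 0, 830 and 0, where edgeR had 376, 1169 and 930 genes with an unadjusted p under 0.05. Without the filter the counts were 33 for α4β7+ CLP against CLP, 80 for ILCP against CILP, and 18 and 96 for Tcf7 knockout CLP and CILP. They were 10 and 47 for Id2 knockout CLP and CILP, 31 and 10 for the interactions, and 3, 174 and 14 for Nfil. Without robust estimation edgeR called 0 for Id2 knockout CLP, 3 for the Tcf7 interaction, and 23 and 2 for Nfil CILP and ILC2P.

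With only the compared groups the counts were 3 for α4β7+ CLP against CLP, 182 for CILP against CLP, 90 for ILC2P against CILP, and 10 and 2 for Tcf7 knockout CILP and ILC2P. They were 1 and 47 for Id2 knockout CLP and CILP, 14 and 12 for the interactions, and 0, 1 and 0 for Nfil. Without the batch term they were 3 for α4β7+ CLP against CLP, 19 for Tcf7 knockout CILP and 3 for the Tcf7 interaction. Batch 1 alone gave 2, 168, 109, 26 and 187 for the first 5 comparisons. It gave 1 for Tcf7 knockout CLP, 9 and 90 for Id2 knockout CLP and CILP, and 20 and 35 for the interactions. Batch 2 alone gave 0, 105, 31, 8 and 93 for the first 5, 0 for Tcf7 knockout CILP, 52 for Tcf7 knockout ILC2P and 0 for the Tcf7 interaction, and the log2 fold change of Cdk1 in Tcf7 knockout CILP was −3.47. Putting the outlier back moved no count by over 1.5 times.

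Without shallow libraries the counts were 326 for ILC2P against CILP, 1 for Tcf7 knockout CLP, 18 for Id2 knockout CILP, and 2 and 197 for Nfil CLP and CILP. Without the doubted libraries they were 1, 2 and 83 for Tcf7 knockout CLP, CILP and ILC2P, 2 and 20 for Id2 knockout CLP and CILP, 0 for the Tcf7 interaction, and 94 and 1 for Nfil CILP and ILC2P. There Cybb (−0.86) and Blnk (−0.011) in Tcf7 knockout CILP, Igha (−3.32), Ighg2b (−4.76) and Hbb-bs (−0.92) in Tcf7 knockout ILC2P, and the Tcf7 interaction of Cybb (−1.76) were negative. Blk in Tcf7 knockout CILP (7.12) and Nkg7 (7.42), Il1r1 (6.89) and Il2rb (8.73) in Tcf7 knockout ILC2P stayed past the threshold. Bcl11b (−4.73), Lmo2 (4.29) and Igfbp4 (−3.06) in Tcf7 knockout CILP did not.

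Leaving out 1 library at a time gave 2 to 6, 353 to 439, 147 to 249, 19 to 52 and 437 to 535 calls for the first 5 comparisons. It gave 0 to 1, 7 to 58 and 85 to 284 for Tcf7 knockout CLP, CILP and ILC2P, 0 to 4 and 1 to 11 for Id2 knockout CLP and CILP, 0 to 8 and 1 to 5 for the interactions, and 1 to 4, 22 to 157 and 1 to 11 for Nfil. Medians of the list of genes higher in CILP ran from −2.81 to −0.47 in the Tcf7 knockout and from −3.02 to −2.37 in the Id2 knockout, and those of the opposite list from 0 to 0.556 and from 0 to 0.895 (0.12 and 0.006 with all libraries). Some log2 fold changes reversed, with ranges of −2.65 to 6.23 for Ccna2 and −0.46 to 10.575 for Hba-a1 in ILCP against CILP, the lowest without ILCP replicate 1. In Tcf7 knockout ILC2P, without replicate 1 or, for Siglech, replicate 2, they ran from −1.025 to 15.867 for Iglc1, −4.85 to 13.922 for Igha, −4.95 to 13.195 for Ighg2b, −0.97 to 9.57 for Hbb-bs, −0.062 to 11.001 for Hba-a1 and −2.79 to 5.88 for Siglech. In Nfil, without replicate 1 of the group, they ran from −2.59 to 9.315 for Ptpn13, −1.07 to 9.01 for Zfp953, −3.96 to 9.94 for Tmem189 and −4.41 to 6.34 for Rrm1.

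Over all settings the 313 named results kept direction and side of the threshold 5880 times, lost the call 1273 times, gained it 11 times and reversed 19 times. No paired analysis was possible because replicate numbers were given in accession order. Depth limits what falls could be seen: ILC2P libraries had 19322 to 80873 counts, so 3 counts in 1 of them make 37.1 to 155.3 CPM. Genes below that level may have few or 0 counts there.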

Other observations

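Across wild-type populations some genes stood higher in CILP than in ILC2P. Cpa3 was at 309 ± 207 and 6.1 ± 13.2 CPM (edgeR adjusted p = 0.000413). The transcriptional cofactor gene Lmo4, chosen after its values were seen, rose from 107 ± 45.5 CPM in CLP and 249 ± 59.1 in α4β7+ CLP to 2547 ± 602 in CILP (adjusted p = 9.05e-14 and 2.14e-06) and was at 563 ± 137 in ILC2P (adjusted p = 0.000157). H2-Eb1, an MHC class II gene, went from 3.2 ± 6.3 CPM in CLP to 158 ± 131 in CILP (adjusted p = 0.000269) and was at 4.3 ± 12.2 in ILC2P (adjusted p = 0.00147).

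The wild-type CILP library left out by the submitters had Trbc1 at 2739.5 CPM (129 counts), Bcl11b at 509.7 CPM (24 counts), Il18r1 at 1125.5 CPM (53 counts) and Flt3 at 0. Id2 was at 84.9 CPM (4 counts) and Ccr2 at 63.7 CPM (3 counts). Its correlation across genes, which are not independent replicates, averaged 0.447 with the 7 other wild-type CILP libraries and 0.412 with CLP, while those 7 had 0.584 with each other.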
